A study of Mus musculus with 4 samples.

How the data were processed

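Nuclei from mouse placenta and decidua at E9.5 and E12.5, after oxycodone or saline, were profiled by combinatorial barcoding in round-1 wells. Per the labels, nuclei were fixed and libraries made with the Parse Evercode WT v2 chemistry, although the description field of the same labels names another platform. The deposited matrices hold counts, which are whole-number UMI counts per nucleus and gene without normalization. The other deposited columns, per the file headers, are identifiers and labels made by the authors' pipeline, which give each nucleus a tissue, a treatment and a round-1 well. Per the labels, the genome was mm10 (GRCm38). The aligner, the counting software and their versions were not stated. The lowest UMI total was 2083 at E9.5 and 2078 at E12.5, so a minimum had been applied before deposition. Each age came as 1 matrix that pools 2 sublibraries, and the median absolute log2 difference between sublibraries was 0.0625 at E9.5 and 0.0778 at E12.5.

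Each age held 12 round-1 wells, 3 for every combination of tissue and treatment, and wells were numbered in the order of the well index within their group. Nothing in the labels says that the wells hold separate animals, so p-values measure the spread between wells. Nuclei with at least 500 UMIs, at least 300 genes and under 10% mitochondrial UMIs were kept. This left 4410 of 4522 nuclei at E9.5 and 2689 of 2905 at E12.5. The kept nuclei had a median of 14842 UMIs and 3608 genes at E9.5 and of 11327 UMIs and 3505 genes at E12.5. Total UMIs per well ranged from 5354890 to 16698206 at E9.5 and from 56899 to 25352386 at E12.5.

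Each age was clustered separately in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering used 15 exact neighbours, resolution 1.0 and seed 0. Scrublet, with an expected rate of 6%, marked 2 nuclei at E9.5 and 1 at E12.5, under the share set for removal, so none were removed. Clusters were named from marker genes of 21 cell types. A name needed at least 3 markers at 20 CPM or more, a log2 rise of at least 1 over the lower quartile of clusters and UMIs in at least 20% of nuclei, and a mean score of at least 1. No other type could have more markers among the 10 leading genes. Another type at over 0.75 of the score, or 0.5 in clusters of high UMIs, barred the name unless the best type had more markers among the 20 leading genes. Clusters scoring best for fibroblast mesenchyme were named decidual stroma where that came next at over 0.75 of the score. Clusters that did not meet these terms stayed unnamed. All names carry the sense of marker-like nuclei. The naming rule was set after the clusters were seen.

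UMIs were summed per well. edgeR 4.0.16 in R 4.3.3 tested genes with filterByExpr, TMM scaling and the quasi-likelihood F-test, and genes at a Benjamini-Hochberg adjusted p under 0.05 were called. DESeq2 1.42.0 was the other tool. Oxycodone was compared with saline in each tissue and age, placenta with decidua at each age with treatment as a covariate, and an interaction of tissue and treatment was tested at each age. The standard error of a log2 fold is the fold divided by the square root of F. Values in CPM are means over wells with the SD over wells. Shares of nuclei were compared by an exact two-sided permutation test of treatment labels within tissue, which has 400 arrangements and a smallest possible p of 0.005. Ages were compared without a test, because age coincides with preparation. Age ratios are of CPM in summed nuclei with a prior count of 1, for genes with at least 100 UMIs over both ages. Intervals are 95% intervals, Clopper-Pearson for shares and conditional binomial for ratios of counts, and cover counting error only. A list's median age ratio was placed among 10000 random lists matched on expression in 20 bins. The profile of parietal trophoblast giant cell (P-TGC)-like nuclei took genes at 50 CPM or more and at least 4 times the level of all other nuclei at both ages.

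The comparisons, tests, gene lists, marker lists and the rule for named genes were fixed before the data were examined. Named genes were the 12 with the smallest adjusted p in each direction, without predicted gene models. Where fewer than 5 passed, the 5 with the smallest p were added. By age they were the 12 largest ratios in each direction, and for the P-TGC-like profile the 24 largest ratios, besides members of the lists. Predicted models are named only where few genes passed, and were chosen after their values were seen. The 14 lists were opioid receptors and peptides, prolactin family hormones, steroid hormone synthesis, angiogenic and vascular factors, endocycle and cell cycle exit, mitotic proliferation, nutrient transport, imprinted genes, hypoxia response, immediate early and heat shock stress, unfolded protein response, interferon and inflammation, extracellular matrix and invasion, and mitochondrial transcripts. Lists were tested with camera in limma 3.58.1 with the preset correlation and again with an estimated correlation. Positions came from the GENCODE annotation of GRCm38, which matched 52029 of the 57010 gene identifiers (91.3%) and gave positions for 604 of 607 named genes.

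Other settings, set in advance, were DESeq2, no expression filter, a minimum of 1000 UMIs, each well left out in turn, clustering at resolutions 0.5 and 2.0, thinning to 1000 UMIs per nucleus before clustering, removal of Scrublet doublets, TMM scaling and a minimum of 20 UMIs for ages. Chosen after seeing the data were a minimum of 5000 UMIs, removal of nuclei above 200000 UMIs, of wells under 80 nuclei and of yolk sac-like and parietal endoderm-like nuclei, placenta or decidua wells alone for ages, a mean of per-nucleus CPM for the P-TGC-like profile, well order as a block, and tests within nucleus classes with at least 10 nuclei in at least 2 wells per arm. The planned P-TGC-like test needed at least 10 nuclei in 2 wells per arm and could not be fitted, so wells with at least 5 such nuclei were used. Recovery was tested on simulated data, with folds of 2 and 4 put into 200 genes. Of genes changed 2-fold and 4-fold, the oxycodone test called 21.3% and 82.8% in placenta and 27.6% and 88.5% in decidua at E9.5. The same figures at E12.5 were 2.11% and 68.0% in placenta and 0% and 5.75% in decidua. For tissue they were 52.6% and 96.7% at E9.5 and 15.7% and 94.6% at E12.5, and for P-TGC-like nuclei 2.17% and 52.7% at E9.5 and 0% and 23.1% at E12.5. Figures were drawn with matplotlib 3.10.9.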

Results

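Single-nucleus RNA sequencing measured nuclear transcripts in mouse placenta and decidua, the maternal lining of the implantation site, at E9.5 and E12.5 after oxycodone, an opioid receptor agonist, or saline. Each age had 12 round-1 wells, with 3 wells each of oxycodone placenta, saline placenta, oxycodone decidua and saline decidua. After filtering, 4410 nuclei remained at E9.5 and 2689 at E12.5. Total UMIs per well ran from 5354890 to 16698206 at E9.5 and from 56899 to 25352386 at E12.5. At E12.5, 5 wells held under 80 nuclei, namely oxycodone placenta 1 (62), saline placenta 3 (74), oxycodone decidua 1 (20), saline decidua 2 (46) and saline decidua 3 (17). The wells, not the nuclei, were the replicates in every test.

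The mix of nuclei by age addressed which placental and decidual lineages were present at each stage. Decidual stroma-like nuclei made up 50.2% of nuclei at E9.5 (95% interval 48.7 to 51.7) and 17.3% at E12.5 (15.9 to 18.8). Endothelium-like nuclei made up 17.3% (16.2 to 18.4) and 10.8% (9.67 to 12.1). The share of parietal trophoblast giant cell (P-TGC)-like nuclei, the giant cells that line the implantation site, was 1.34% (1.02 to 1.72) at E9.5 and 2.45% (1.90 to 3.11) at E12.5. Trophoblast classes named at E12.5 alone were glycogen trophoblast (10.2%), spongiotrophoblast (6.32%), sinusoidal giant cell (5.47%), syncytiotrophoblast I (5.09%), chorion and labyrinth progenitor (4.72%) and syncytiotrophoblast II (2.94%). Clusters left unnamed included cluster 1 (12.9%) and cluster 8 (3.65%), led by genes of trophoblast, at E9.5 and cluster 1 (9.71%) at E12.5. A class without a name at E9.5 was therefore not shown to be absent. The intervals of 6 of the 9 classes named at both ages did not overlap, but only 2 of 5 after thinning every nucleus to 1000 UMIs. No test of age was run, since age coincides with preparation, and placenta wells gave 2491 of 4410 nuclei at E9.5 and 2030 of 2689 at E12.5. Within placenta wells decidual stroma-like nuclei were 29.4% at E9.5 and 6.01% at E12.5, and in decidua wells 77.1% and 52.2%. Endothelium-like nuclei moved in opposite ways, from 23.4% to 6.85% in placenta wells and from 9.33% to 23.1% in decidua wells. P-TGC-like nuclei overlapped in placenta wells, at 2.01% (1.49 to 2.64) and 2.27% (1.66 to 3.01), and in decidua wells were 0.469% and 3.03%. Of the 20 such nuclei in decidua wells at E12.5, 4 lay in oxycodone decidua 1 and 5 in saline decidua 3. Those wells held only 20 and 17 nuclei of any class. All 101 uterine natural killer-like nuclei at E9.5 lay in placenta wells.

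**Figure D1:**
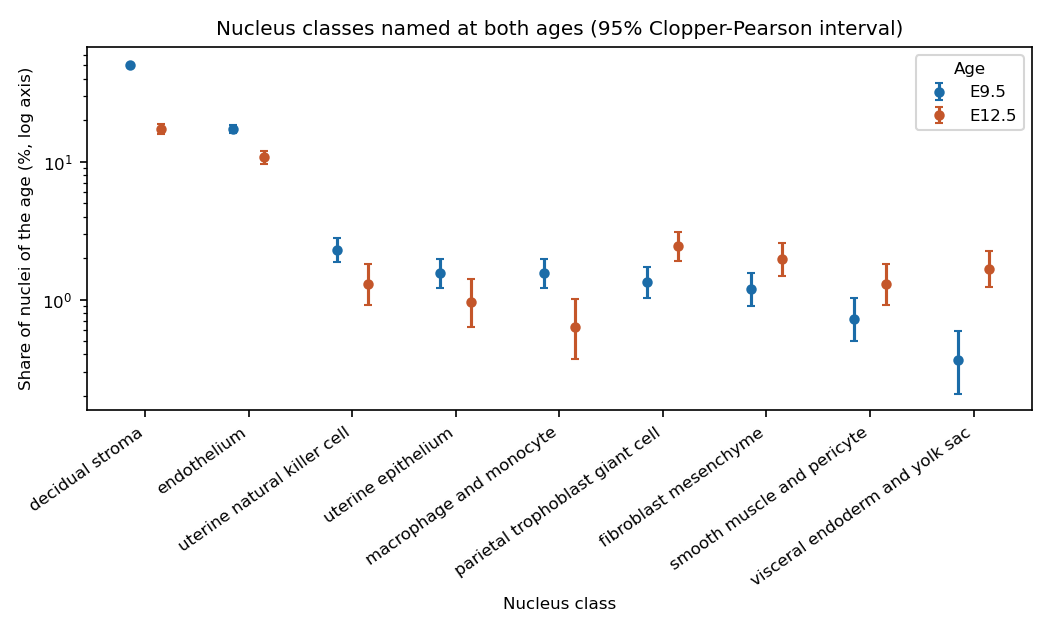
Share of nuclei in each class named at both ages, in percent at E9.5 and E12.5 on a log axis, with 95% Clopper-Pearson intervals as error bars. Decidual stroma-like nuclei are at 50.2% at E9.5 and 17.3% at E12.5.

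The profile of P-TGC-like nuclei addressed the stated aim of describing these cells. The class held 59 nuclei at E9.5 and 66 at E12.5, and was defined by prolactin family and Hand1 markers, so high levels of those genes state its identity. Prl2c2, a prolactin family hormone and marker (ENSMUSG00000079092, chromosome 13, 12996125 to 13005383), stood at 983 CPM against 5.75 in all other nuclei at E9.5 and at 1019 against 28.5 at E12.5. Outside the markers, Tfpi, an inhibitor of the tissue factor clotting pathway (ENSMUSG00000027082, chromosome 2, 84432855 to 84476775), stood at 8518 CPM against 176 at E9.5 and at 8566 against 585 at E12.5. Star, which moves cholesterol into mitochondria for steroid synthesis, had log2 ratios of 6.73 and 4.38, and Fdx1, an electron donor of that synthesis, 3.44 and 2.26. Keratin gene Krt8 had log2 ratios of 3.42 and 2.65, desmosome gene Pkp3 6.70 and 3.32, and Prom2 7.87 and 4.66. In all, 40 genes were at least 4 times as high as in other nuclei at both ages.

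Of the steroid hormone synthesis list, 8 of 11 measured members were at least 2 times as high in P-TGC-like nuclei at E9.5 and 2 were lower (median log2 ratio 3.44), and at E12.5 6 were higher and 2 lower of 11 (1.16). Prolactin family hormones split 13 higher and 6 lower of 20 at E9.5 (2.42) and 12 and 5 of 21 at E12.5 (1.37). Endocycle genes were 11 higher and 2 lower of 13 at E9.5 (2.54) and 1 higher and 0 lower at E12.5 (0.01), with Ccne1, the cyclin that drives endocycles, at a log2 ratio of 4.04 at E9.5 and -0.45 at E12.5. Imprinted genes were 12 higher and 4 lower of 17 at E9.5 (2.94) and 1 and 8 of 18 at E12.5 (-0.15). The other nuclei also changed with age, so these ratios do not trace the class alone. From E9.5 to E12.5 imprinted genes had a median log2 ratio of 0.14 within P-TGC-like nuclei and 2.94 over all nuclei. Endocycle genes had -0.86 and 1.12, and mitotic genes -0.62 and 1.36. Angiogenic and vascular factors were 1 higher and 11 lower of 13 at E9.5 (-2.43) and 0 and 12 of 14 at E12.5 (-2.18). Mitotic genes were 7 and 0 of 12, then 0 and 3, interferon genes 0 and 7 of 10, then 0 and 3 of 7, stress genes 5 and 5 of 13, then 8 and 3, extracellular matrix genes 5 and 8 of 16, then 3 and 6 of 14, and mitochondrial transcripts 0 and 5 of 8, then 0 and 0. Nutrient transport gave 3 and 4 of 12, then 0 and 3, hypoxia 1 and 4 of 12, then 0 and 3 of 13, the unfolded protein response 0 and 3 of 11, then 0 and 2 of 10, and opioid genes 0 and 1 of 2 at each age.

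Prl3d1, the placental lactogen of early giant cells (ENSMUSG00000057170, chromosome 13, 27094190 to 27100258), exceeded 100 CPM in 42.4% of P-TGC-like nuclei and 2.32% of others at E9.5, with median depths of 22468 and 14779 UMIs. At E12.5 it did so in 0 of 66 P-TGC-like nuclei and 0.343% of others, but the depths turned, with medians of 6726 and 11346 UMIs. Of the 66 nuclei, 41 held under 20000 UMIs. A few nuclei with very many UMIs weighed on these sums, and their size was not measured. Over all classes, 48 nuclei at E9.5 and 50 at E12.5 were above 200000 UMIs. In P-TGC-like nuclei those above 200000 UMIs were 4 with 54.5% of the class's UMIs at E9.5 and 11 with 80.4% at E12.5. Without them 17 genes met the 4-fold rule, of which 12 were among the 40 met with them. The smaller log2 ratio of the ages then was 3.11 for Prl2c2, 2.56 for Tfpi, 2.81 for Star, 3.39 for Prom2 and 2.00 for Pkp3, and Krt8 (1.86) and Fdx1 (1.73) no longer met the rule.

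**Figure D2:**
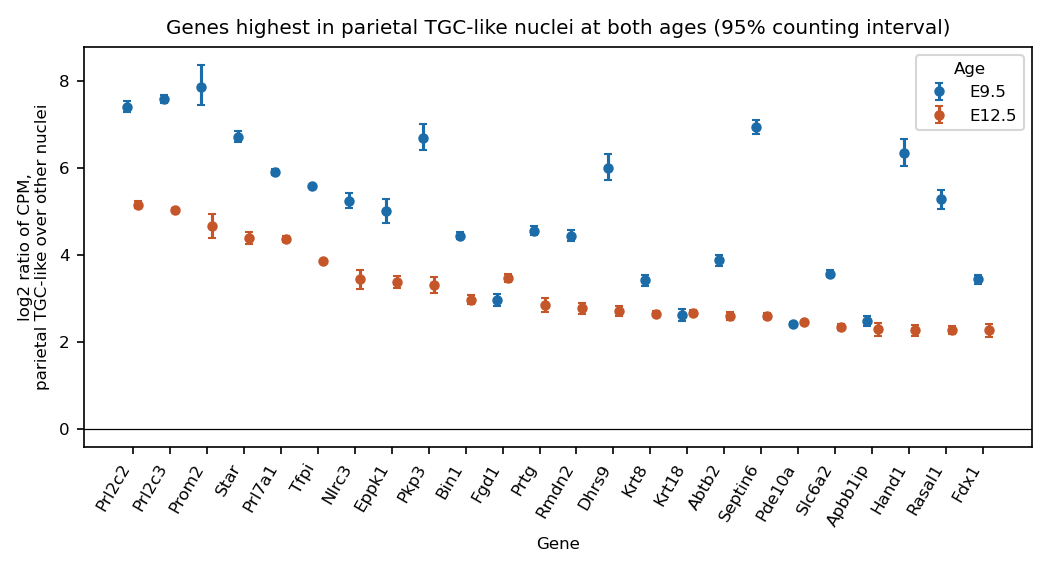
Log2 ratio of CPM in parietal trophoblast giant cell-like nuclei over all other nuclei for the 24 named genes, with E9.5 and E12.5 side by side and 95% counting intervals. Prl2c2 is at 7.42 at E9.5 and 5.16 at E12.5.

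Whether oxycodone changed placental genes at E9.5 was tested in 3 oxycodone against 3 saline wells. No gene passed, with 0 of 15123 in edgeR, and 2 higher and 13 lower in DESeq2, and 1 passed in edgeR without oxycodone placenta 2. In edgeR 465 genes had an unadjusted p under 0.05, where chance gives 756. The smallest p belonged to Ltf, the iron-binding lactotransferrin secreted by uterine epithelium (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), at 0.752 ± 0.236 CPM with oxycodone and 19.9 ± 17.3 with saline (SD, n = 3 wells each). Its log2 fold in edgeR was -4.73 (SE 0.763, adjusted p = 0.999), and it was lower in all 3 oxycodone wells than in every saline well. Ccdc33 had a log2 fold of -3.10, Ephb1, an ephrin receptor, -2.62, Maged2 -1.59 and Crybg3 -0.76 without passing. Medians were below 0 for imprinted genes (-0.58; 0 of 17 passed), prolactin family hormones (-1.14; 0 of 17) and steroid hormone synthesis (-0.66; 0 of 11, and 1 adjusted over the list alone). The preset camera test called these lists lower (adjusted p = 2.01e-10, 0.00226 and 5.21e-06), and with an estimated correlation the adjusted p = 0.403, 0.671 and 0.403 in that order. The share of P-TGC-like nuclei, which express many genes of the hormone lists, was 1.43 ± 1.03% in oxycodone and 2.44 ± 1.25% in saline placenta wells (SD, n = 3). All 4 nuclei of this class above 200000 UMIs, with 54.5% of its UMIs, lay in saline placenta wells. The nucleus with the most UMIs alone held 14.1% of the UMIs of saline placenta 2. The lists were tested on summed UMIs, and the part of these nuclei in the list results was not tested. In the other 11 lists 0 members passed, and mitotic genes had a median of 0.03 while camera pointed down. Of simulated 2-fold changes the test found 21.3% in these wells.

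In decidua at E9.5 the same question gave 0 of 14132 genes in edgeR, and 6 higher and 13 lower in DESeq2. In edgeR 465 genes had an unadjusted p under 0.05, where chance gives 707. Ltf again had the smallest p, at 3.92 ± 0.635 CPM with oxycodone and 18.1 ± 4.47 with saline (SD, n = 3), a log2 fold of -2.25 (SE 0.233, edgeR adjusted p = 0.241). DESeq2 called it, with an adjusted p of 2.56e-10. Taco1, a translational activator of a mitochondrial respiratory subunit, stood at 150 ± 76.2 and 19.2 ± 6.47 CPM, and Tmem150a, Gse1 and the guidance receptor Robo2 had log2 folds of 1.09, 0.89 and -1.04 without passing in edgeR. Mitochondrial transcripts had a median of 0.62 (0 of 8 passed, 1 adjusted over the list alone) and imprinted genes -0.49 (0 of 13, and 1 adjusted over the list alone). Camera called the former higher and the latter lower (adjusted p = 5.19e-09 and 0.000166), and with an estimated correlation both had adjusted p = 0.501. In the other 11 lists 0 members passed (1 of the stress genes adjusted over the list alone), and median and camera differed in sign for hypoxia (0.01, down) and nutrient transport (-0.04, up). The interaction of tissue and treatment gave 0 of 16083 genes in edgeR at E9.5, and was not run in DESeq2. It gave 381 genes at an unadjusted p under 0.05, where chance gives 804.

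**Figure D3:**
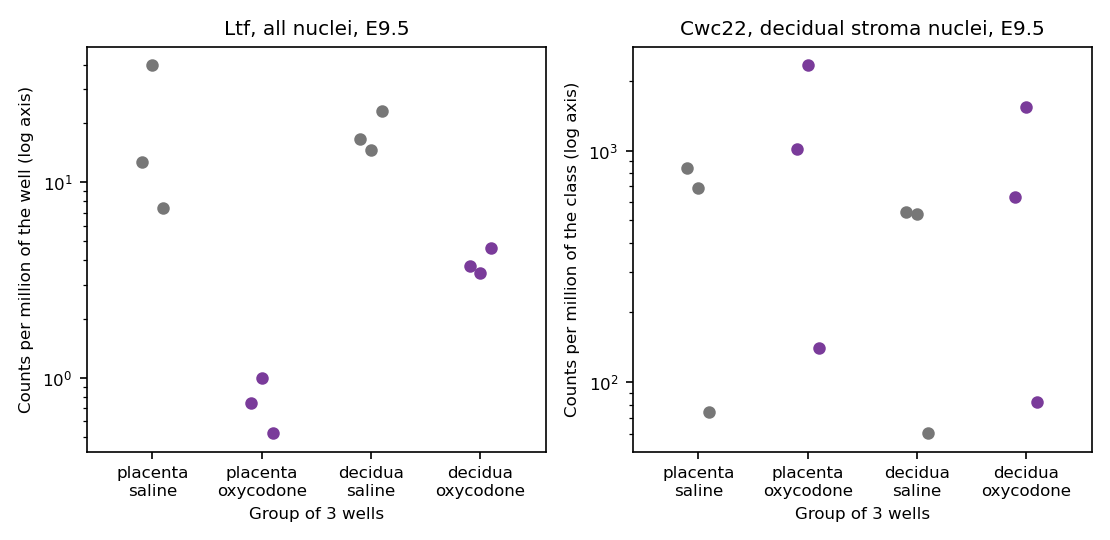
CPM per well at E9.5 of Ltf in all nuclei and of Cwc22 in decidual stroma-like nuclei, 1 point per well, by tissue and treatment. Ltf lies between 0.521 and 4.64 in the 6 oxycodone wells and between 7.36 and 39.6 in the 6 saline wells.

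At E12.5 in placenta, 7 genes rose with oxycodone and 0 fell, of 16079 tested in edgeR. Ttr, the thyroid hormone carrier transthyretin (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), was at 12.4 ± 6.04 CPM with oxycodone and 0.267 ± 0.27 with saline (SD, n = 3), a log2 fold of 5.11 (SE 0.544, edgeR adjusted p = 0.00553). Its counts were 535 and 14 UMIs, a ratio of 40.6 (95% counting interval 24 to 74.7). Fga, which encodes a fibrinogen chain (ENSMUSG00000028001, chromosome 3, 83026076 to 83033627), rose by 4.64 ± 0.684 (SE), and Hnf4aos, antisense to the endoderm regulator Hnf4a (ENSMUSG00000046840, chromosome 2, 163493807 to 163541720), by 4.84 ± 0.717. Col2a1, a cartilage collagen (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695), rose by 4.95 ± 0.768 and Pde6c, a cone phosphodiesterase (ENSMUSG00000024992, chromosome 19, 38132781 to 38183958), by 4.68 ± 0.727. The predicted transcripts 4930405D11Rik (chromosome 11, 90804692 to 90895149) and Gm13727 (chromosome 2, 77879753 to 77881467) rose by 4.75 and 4.41, and Gm13727 overlaps the end of Cwc22 on the same strand by 309 bases. All but Ttr had an adjusted p of 0.0491 in edgeR.

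Yolk sac-like nuclei, which express Ttr and Afp, were 2.81 ± 2.63% of nuclei in oxycodone and 0.0766 ± 0.133% in saline placenta wells, and parietal endoderm-like nuclei 7.29 ± 6.31% and 2.07 ± 1.80% (SD, n = 3). Without both classes of nuclei 0 genes passed, with a median log2 fold of means of 2.67 for the 7 genes against 3.14 with them. Of the 7 called genes, 5 were higher in every oxycodone well than in every saline well, and Hnf4aos and 4930405D11Rik had 0 UMIs in oxycodone placenta 1. In that well the 5 genes had few UMIs, with 1 for Gm13727, 2 for Ttr and Fga, and 3 for Col2a1 and Pde6c. Gm13727 also had 1 UMI in saline placenta 3. DESeq2 called 7 genes, 1 of them shared (Ttr). In edgeR 892 genes had an unadjusted p under 0.05, where chance gives 804. Single wells decided the count, which was 42 without oxycodone placenta 1, 1 without oxycodone placenta 2, 13 without oxycodone placenta 3, 0 without saline placenta 1 or saline placenta 2, and 107 without saline placenta 3. Of the lists, camera called interferon and inflammation higher (median 0.85, 0 of 7 passed, 1 adjusted over the list alone; adjusted p = 0.0282), and with an estimated correlation the adjusted p = 0.854. In the other 12 lists 0 members passed, and hypoxia genes had a median of 0.08 while camera pointed down.

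**Figure D4:**
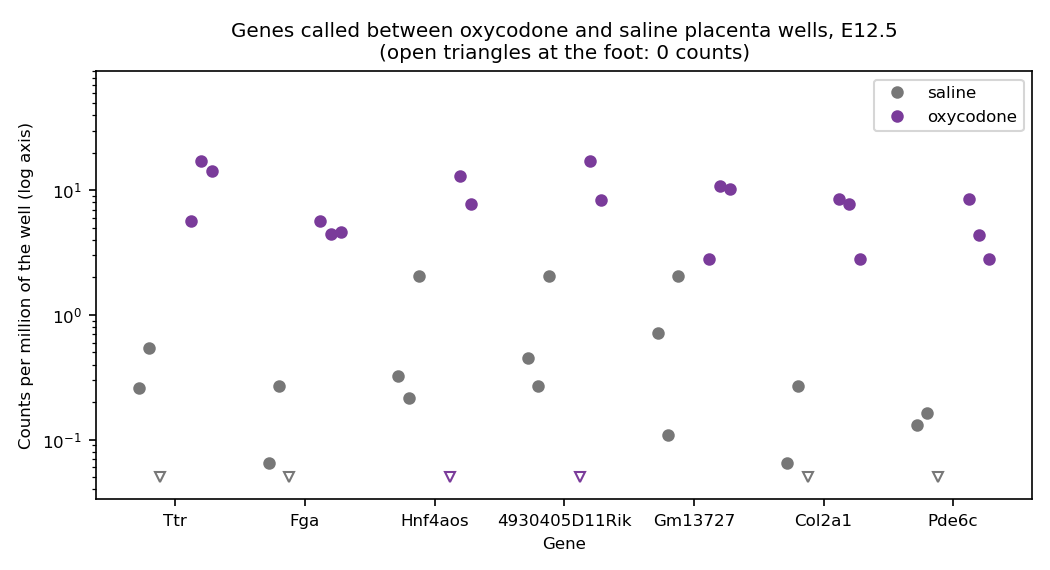
CPM per placenta well at E12.5 of the 7 genes that passed the edgeR test, on a log axis, with oxycodone and saline wells as separate points. Ttr averages 12.4 in the oxycodone wells and 0.267 in the saline wells.

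In decidua at E12.5, 0 of 8158 genes passed in edgeR and 0 were called by DESeq2. In edgeR 75 genes had an unadjusted p under 0.05, where chance gives 408. The genes with the smallest p were Hs6st3, a heparan sulfate sulfotransferase, at 65.8 ± 30.4 CPM with oxycodone and 14.9 ± 3.72 with saline (SD, n = 3; log2 fold 2.01), and Arfgef3 (-1.94), Kank3 (1.54), Slc35f3 (2.41) and Nexn (-1.33). Camera called extracellular matrix and invasion genes higher (median 0.40, 0 of 12 passed) and mitochondrial transcripts lower (-0.85, 0 of 8), both at adjusted p = 0.00644, and with an estimated correlation both had adjusted p = 0.722. In the other 11 lists 0 members passed, and camera pointed down for angiogenic factors (median 0.03) and interferon genes (0.13). In simulated data for these wells the test found 5.75% of 4-fold changes, so changes of that size would mostly be missed here. The interaction gave 0 of 11838 genes in edgeR at E12.5, with 278 at an unadjusted p under 0.05, where chance gives 592.

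In P-TGC-like nuclei at E12.5, 25 genes rose with oxycodone and 1 fell, of 7794 tested over 2 placenta wells and 1 decidua well per arm with at least 5 such nuclei, with tissue as a covariate. The wells differed in nucleus quality. The median mitochondrial share was 3.64% in oxycodone placenta 3 and 3.85% in oxycodone decidua 3 but 0.221% in oxycodone placenta 2, and 0.242% to 0.672% in the saline wells. Abtb2, a BTB-domain gene that is also in the profile of this class (ENSMUSG00000032724, chromosome 2, 103566310 to 103718423), was at 378 ± 119 CPM against 28.7 ± 28.1 (SD, n = 3), a log2 fold of 4.91 (SE 0.551, edgeR adjusted p = 0.00722). Lrrk2, a kinase gene linked to Parkinson disease, rose by 3.89, Gfpt2, which feeds the hexosamine pathway, by 4.34, Plcg2, a phospholipase, by 5.14 and Dhcr7, the last enzyme of cholesterol synthesis, by 4.98. Fosb, an immediate early gene, had 113 UMIs against 1, a ratio of 91.7 (16.1 to 3655), and Prl8a6 had 527 against 3, a ratio of 143 (48.5 to 694). All 8 mitochondrial transcripts passed when adjusted over the list alone and 1, mt-Nd1, over all genes (median 4.01). Camera called higher mitochondrial transcripts (adjusted p = 3.91e-10), stress genes (3.93e-06), endocycle genes (4.06e-05), extracellular matrix genes (5.95e-05) and the unfolded protein response (0.0141). With an estimated correlation the adjusted p = 0.347, 0.340, 0.340, 0.347 and 0.347 in that order. 1 member each passed over all genes of the extracellular matrix, stress and prolactin lists, and adjusted over the list alone 2 of 9, 5 of 8 and 1 of 13 did, with prolactin genes at a median of -0.47 while camera pointed up. Adjusted over the list alone, 3 members passed in each of the endocycle, imprinted, mitotic, nutrient transport and unfolded protein response lists, 2 of steroid synthesis, 1 of angiogenic factors, 1 of hypoxia and 0 of interferon genes. The wells held 16381 to 1962180 UMIs of this class.

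The count in this class rested on single wells and on nuclei with very many UMIs. It was 0 without oxycodone decidua 3 or saline decidua 3, 429 without oxycodone placenta 2, 78 without oxycodone placenta 3, 148 without saline placenta 2, and 3 without nuclei above 200000 UMIs. DESeq2 called 66 higher and 11 lower. At E9.5 edgeR called 0 of 6799 genes in this class with 2 wells per arm, with 398 at an unadjusted p under 0.05 and 20 lower in DESeq2, and 47 were called without oxycodone placenta 2 and 45 without saline placenta 3, each of which left 1 well in an arm. Chance gives 340 genes at an unadjusted p under 0.05 in this test. The smallest p belonged to Hdac9, a histone deacetylase, with a log2 fold of -3.35 (edgeR adjusted p = 0.0906). The wells used at E9.5 differed as well. The median mitochondrial share was 0.104% in oxycodone placenta 2 and 0.0421% to 0.0543% in the others. Nuclei of this class above 200000 UMIs lay only in the saline wells, 1 in each. At E9.5 camera called endocycle genes (adjusted p = 0.0064), the unfolded protein response (0.0064) and mitochondrial transcripts (0.00241) higher, and extracellular matrix (2.37e-05) and prolactin genes (1.24e-05) lower. With an estimated correlation each of these had an adjusted p = 0.397. No list member passed over all genes. Adjusted over the list alone, 4 of 9 extracellular matrix genes passed, 3 prolactin genes, 3 nutrient transport genes (median 0.22, but camera pointed down), and 1 each of angiogenic, hypoxia and steroid synthesis genes.

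Within other classes, tested after the classes were seen, few genes passed at E9.5. In endothelium-like nuclei of placenta Chrdl1, a secreted BMP antagonist (ENSMUSG00000031283, chromosome X, 143285674 to 143394262), fell by 4.97 on the log2 scale, at 1.16 ± 0.126 against 38.6 ± 15.6 CPM (SD, n = 3, edgeR adjusted p = 0.0189). This was 1 of 8387 genes, with 329 at an unadjusted p under 0.05, where chance gives 419, and 20 called by DESeq2. The count was 0 without oxycodone placenta 2 or saline placenta 2, 4 without oxycodone placenta 1 and 3 without saline placenta 3. Without oxycodone placenta 3 another gene passed and Chrdl1 did not (edgeR adjusted p = 0.0635). In edgeR 0 genes passed in decidual stroma-like nuclei of placenta (228 at an unadjusted p under 0.05, 0 in DESeq2) and of decidua (519 and 11), in endothelium-like nuclei of decidua (198 and 5, with 3 genes in edgeR without oxycodone decidua 1) and in the trophoblast-like cluster 8 (276 and 5). Chance gives 475, 653, 213 and 418 genes at an unadjusted p under 0.05 in that order. At E12.5, with 2 wells per arm, Cwc22, a splicing factor gene (ENSMUSG00000027014, chromosome 2, 77881159 to 77946375), rose in every named trophoblast class tested. The log2 folds were 4.07 ± 0.319 (SE) in chorion and labyrinth progenitor, 4.04 ± 0.283 in glycogen trophoblast, 4.08 ± 0.227 in sinusoidal giant cell and 3.62 ± 0.331 in spongiotrophoblast-like nuclei. Its level in all nuclei of E12.5 placenta was 293, 1377 and 1006 CPM in the oxycodone wells and 129, 79.5 and 217 in the saline wells. The arms were not apart in E12.5 decidua, at 949, 1424 and 291 CPM with oxycodone and 1568, 71.1 and 1125 with saline.

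The yolk sac gene Afp, which encodes alpha-fetoprotein, rose by 5.78 in glycogen trophoblast and 5.76 in spongiotrophoblast-like nuclei at E12.5, where it was far below its 7303 CPM in yolk sac-like nuclei of oxycodone placenta. In these classes 2 genes passed in chorion and labyrinth progenitor, 2 in glycogen trophoblast, 1 in sinusoidal giant cell and 4 in spongiotrophoblast-like nuclei. Parietal endoderm-like nuclei had 111 genes higher and 21 lower, with Grem2, a BMP antagonist, at 3.06 ± 0.392 (SE) and Rgs6, a regulator of G protein signalling, at -2.66 ± 0.336. This class joined clusters 11 and 22, which held 51 and 22 nuclei in oxycodone placenta 2, 22 and 2 in oxycodone placenta 3, 7 and 7 in saline placenta 1 and 4 and 13 in saline placenta 2. Grem2 was a leading gene of cluster 11, and the calls were not separated from this mix. In edgeR 0 genes passed in endothelium-like nuclei of placenta (658 at an unadjusted p under 0.05, 116 in DESeq2) and in decidual stroma-like nuclei of decidua (244 and 1). Chance gives 323 and 372 genes at an unadjusted p under 0.05 in that order.

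Leaving out a well in these E12.5 classes left a single well in 1 arm and moved every count. Without oxycodone placenta 2, oxycodone placenta 3, saline placenta 1 and saline placenta 2 in turn, edgeR called 1, 10, 38 and 25 genes in chorion and labyrinth progenitor, 4, 37, 32 and 15 in glycogen trophoblast, and 4, 9, 11 and 4 in sinusoidal giant cell-like nuclei. In the same order the counts were 74, 46, 8 and 0 in spongiotrophoblast, 335, 194, 384 and 209 in parietal endoderm and 323, 206, 82 and 258 in endothelium-like nuclei. Decidual stroma-like nuclei of decidua gave 36 without oxycodone decidua 2, 35 without oxycodone decidua 3, 13 without saline decidua 1 and 1 without saline decidua 2.

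Whether oxycodone shifted the mix of nuclei was tested by exact permutation within tissue, 3 wells per group. No class passed, but a single changed class could not have passed, because the smallest adjusted p it can reach is 0.065 over 13 classes at E9.5 and 0.105 over 21 at E12.5. The smallest adjusted p found were 0.416 and 0.939, and the test leaves open whether single classes changed. Decidual stroma-like nuclei at E9.5 were 30.6 ± 10.3% with oxycodone and 29.9 ± 10.9% with saline in placenta, and 77.7 ± 4.88% and 77.2 ± 2.18% in decidua (SD, n = 3).

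The comparison of placenta with decidua asked which genes mark each tissue, with 6 wells each. At E9.5, 4183 genes were higher in placenta and 3639 lower, of 15553 in edgeR. Arap1, a GTPase-activating protein of endosomes (ENSMUSG00000032812, chromosome 7, 101348067 to 101412586), was at 199 ± 26.9 CPM in placenta and 19.5 ± 2.23 in decidua (SD, n = 6), a log2 fold of 2.86 (SE 0.118, edgeR adjusted p = 9.26e-08). Among the most significant genes higher in placenta were also Kit, the stem cell factor receptor (2.45), Pros1, the anticoagulant protein S (2.00), and Dsc2, a desmosomal cadherin (5.30). Phldb2, a cell cortex protein gene (ENSMUSG00000033149, chromosome 16, 45746243 to 45953598), was lower in placenta with a log2 fold of -2.35 (SE 0.107), as were the aggrecanase Adamts5 (-4.40), the vitamin C transporter Slc23a2 (-2.17), the bradykinin receptor Bdkrb2 (-2.77) and the protease inhibitor Tfpi2 (-3.98). Decidual stroma-like nuclei were 29.4% of placenta and 77.1% of decidua nuclei. DESeq2 called 4614 higher and 4095 lower.

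By list at E9.5, imprinted genes were 14 higher and 0 lower of 17, such as Igf2, a fetal growth factor (3.14 ± 0.478, SE), and Peg10 (4.22). Mitotic genes were 11 higher and 0 lower of 12, such as Mki67 (1.82 ± 0.197) and Top2a (2.02), endocycle genes 9 and 0 of 13, such as Ccne1 (2.89), and interferon and inflammation genes 7 and 0 of 9, such as Stat1 (1.05) and Irf1 (1.31). The unfolded protein response was 0 higher and 10 lower of 11, such as Dnajb9 (-2.04 ± 0.25) and Chac1 (-2.22), and steroid hormone synthesis 7 and 0 of 11, such as the progesterone-degrading Akr1c18 (3.03). Camera called these 6 lists at adjusted p = 1.01e-05, 1.37e-07, 0.00197, 0.00289, 0.000314 and 0.038, and with an estimated correlation the adjusted p = 0.196, 0.190, 0.196, 0.190, 0.190 and 0.449. Adjusted over the list alone, 14, 11, 10, 8, 11 and 7 members passed. Prolactin hormones were 8 higher and 4 lower of 19 (13 adjusted over the list alone), with decidual Prl8a2 at -3.54 and giant cell Prl3d1 at 2.27. The remaining lists gave 6 higher and 6 lower of 16 for extracellular matrix (12 adjusted over the list alone; median 0.49, but camera pointed down), 6 and 3 of 12 for hypoxia (9), 6 and 2 of 12 for nutrient transport (8), 3 and 1 of 14 for angiogenic factors (4), 3 and 0 of 12 for stress genes (3), 0 and 2 of 8 for mitochondrial transcripts (2), and 1 and 0 of 2 for opioid genes (1), the opioid peptide gene Penk at 2.67 ± 0.442.

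At E12.5, 1114 genes were higher in placenta and 1688 lower, of 11223 in edgeR. Platr20, a noncoding RNA (ENSMUSG00000086646, chromosome 11, 51189833 to 51220418), was at 31.5 ± 8.66 CPM in placenta and 0.967 ± 1.15 in decidua (SD, n = 6), a log2 fold of 3.95 (SE 0.398, edgeR adjusted p = 0.000604). The pregnancy-specific glycoprotein Psg21 (4.21), the R-spondin receptor Lgr5 (4.47) and the semaphorin receptor Plxnb1 (3.61) were also higher. Cd96, a receptor of natural killer and T cells (ENSMUSG00000022657, chromosome 16, 46035657 to 46120251), had a log2 fold of -4.75 (SE 0.536), and Hsd11b1, which activates glucocorticoids, -3.35, Vegfd, a lymphatic growth factor, -4.26, and the uterine patterning gene Hoxa11 -3.97. DESeq2 called 1638 higher and 3057 lower. Leaving out saline decidua 1 gave 1601 genes in edgeR, and the count was 5758 without the 5 wells under 80 nuclei.

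By list at E12.5, angiogenic and vascular factors were 1 higher and 8 lower of 12, such as the nitric oxide synthase Nos3 (-2.40) and Edn1, which encodes endothelin (-2.58), with the VEGF receptor Flt1 higher (1.75). Endothelium-like nuclei, which express Nos3 and Edn1, were 6.85% of placenta and 23.1% of decidua nuclei at E12.5, and decidual stroma-like nuclei 6.01% and 52.2%. Mitotic genes were 8 higher and 0 lower of 11, such as Top2a (1.58), endocycle genes 6 and 2 of 12, interferon and inflammation genes 0 and 5 of 6, such as Tlr4 (-2.92) and Irf1 (-1.63), imprinted genes 4 and 0 of 17, such as Cdkn1c (2.51), and prolactin hormones 4 and 1 of 18, such as Prl8a8 (2.75). Camera called these 6 lists at adjusted p = 0.00195, 0.000695, 0.00744, 0.00674, 0.00171 and 0.0221, and with an estimated correlation the adjusted p = 0.414, 0.508, 0.508, 0.508, 0.673 and 0.673. Adjusted over the list alone, 10, 10, 9, 5, 7 and 9 members passed. Irf1 and Akr1c18 had opposite signs at the ages, Akr1c18 at 3.03 at E9.5 and -4.82 at E12.5, a difference that was not tested. The classes turned with them, as uterine natural killer-like nuclei were 4.05% of placenta and 0% of decidua nuclei at E9.5 but 0.296% and 4.40% at E12.5, and endothelium-like nuclei 23.4% and 9.33% at E9.5. The remaining lists gave 4 higher and 2 lower of 10 for steroid synthesis (6 adjusted over the list alone), 0 and 5 of 12 for hypoxia (5), 1 and 4 of 13 for extracellular matrix (7; median 0.03, but camera pointed down), 0 and 2 of 9 for stress genes (3), 0 and 3 of 12 for nutrient transport (5; median 0.13, but camera pointed down), 0 and 1 of 9 for the unfolded protein response (4), and 0 and 0 of 8 for mitochondrial transcripts (0; median -0.09, but camera pointed up).

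The comparison of ages asked how each gene's level moved between E9.5 and E12.5, without a test. Over all nuclei, 4686 genes were at least 2 times as high at E12.5 and 2162 at most 0.5 times as high, of 17768, around a median log2 ratio of 0.43. With TMM scaling the split was 2881 and 3296. Among the genes with the largest ratios, Ceacam5 went from 0.123 to 490 CPM and the cathepsin genes Cts3 and Ctsm, expressed in trophoblast, from 0.311 to 704 and from 0.458 to 916. Among the genes that were lower, A2m, a protease inhibitor made by decidua, went from 3976 to 43.6 CPM and the chemokine Cxcl14 from 47.4 to 0.35. Imprinted genes were 17 higher and 0 lower of 19 (median log2 ratio 2.94), prolactin hormones 16 and 6 of 24 (2.04), mitotic genes 12 and 0 of 12 (1.36) and mitochondrial transcripts 7 and 0 of 8 (1.58), at percentiles 100, 100, 99.74 and 99.81 of random lists. Angiogenic factors were 3 higher and 3 lower of 14 (-0.30, percentile 0.92). Other lists gave 8 and 1 of 13 for endocycle genes (1.12), 5 and 2 of 12 for nutrient transport (0.77), 6 and 4 of 16 for extracellular matrix (0.53), 4 and 0 of 13 for hypoxia (0.23), 4 and 4 of 11 for steroid synthesis (0.25), 2 and 2 of 11 for the unfolded protein response (-0.15), 0 and 3 of 11 for interferon genes (-0.13), 2 and 1 of 13 for stress genes (0.04) and 1 and 1 of 3 for opioid genes (0.55). Trophoblast-rich placenta wells gave a larger part of the nuclei at E12.5.

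Within decidual stroma-like nuclei 2304 genes were higher and 1130 lower of 13069 (1206 and 1999 with TMM; median 0.31), and the lipase Lipg and the neuropeptide Nmu were lower, with log2 ratios of -7.05 and -6.05. Cts3, a trophoblast gene, had 0 UMIs in these nuclei at E9.5 and 168 CPM at E12.5, against 704 in all nuclei, and 229 in endothelium-like nuclei. In endothelium-like nuclei 1128 genes were higher and 474 lower of 9811 (976 and 676 with TMM, 941 and 742 with median ratio factors), and Penk and Il6 were lower, with log2 ratios of -4.38 and -4.32. In P-TGC-like nuclei 942 were higher and 1153 lower of 8026 (1013 and 1069 with TMM), and with median ratio factors the balance turned, at 1092 and 977. In this class Prl3d1 went from 703 to 3.93 CPM, a log2 ratio of -7.42 (-8.18 to -6.87), Prl3b1 from 1.54 to 619 CPM and Prl7a2 from 0.257 to 299. Its median depth was 22468 UMIs at E9.5 and 6726 at E12.5. Prolactin hormones had a median of 2.01 in this class, and of 3.79 in decidual stroma-like and 4.03 in endothelium-like nuclei. Their rise was thus not particular to P-TGC-like nuclei, and its source was not tested. In P-TGC-like nuclei extracellular matrix genes were 5 higher and 1 lower of 9 (median 2.79, percentile 100), and steroid synthesis genes 0 and 6 of 9 (-1.25, percentile 0.02). Without nuclei above 200000 UMIs the count for P-TGC-like nuclei fell from 2095 to 1108.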

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

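The outlier tests and most tests of causes below were set before their results were seen. The tests of Cwc22 and of yolk sac RNA in other nuclei, the ratios of C3 and Lcn2 and the overlap of Gm13727 with Cwc22 were chosen after the result was seen.

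Among 96 groups of 6 wells, 10 had 1 well far from the others by the ratio of its gap to the group's range (Dixon test, 95% limit), and chance gives about 1 in 20 such groups, or 4.8 here. At E9.5 these were Nlrc5 in oxycodone placenta 2 (ratio 0.745), Adamts5 in saline placenta 2 (0.717) and Tfpi2 in saline placenta 1 (0.920). At E12.5 they were Septin4 in saline decidua 3 (0.639), Shisal1 in saline placenta 3 (0.702), Efs in oxycodone placenta 1 (0.658), Lgr5 in oxycodone placenta 1 (0.702), Traf1 in oxycodone decidua 1 (0.757), Hoxd10 in saline decidua 3 (0.735) and Vegfd in oxycodone placenta 1 (0.726). All 7 at E12.5 lay in wells of under 80 nuclei. Among 84 pairs of groups, 1 had every well moving in opposite ways, Hs6st3 in decidua, with log2 folds of -2.13 at E9.5 and 2.00 at E12.5, a difference of -4.13 that was not tested.

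The 7 genes that rose in E12.5 placenta were weighed against a different mix of nuclei. If endoderm-like nuclei in the oxycodone wells were the source, their removal should have brought the median log2 fold of the 7 genes near 0, and it was 2.67, against 3.14 with them, although 0 genes then passed. Removal of the wells of under 80 nuclei gave 3.6, which argues against thin wells as the source. For yolk sac RNA in other nuclei, 5 of the 7 genes were at least 4 times as high in yolk sac-like nuclei as in others. Any yolk sac gene would meet this, and Ttr is a marker of the class, so it does not show leaked RNA. Afp was at 139 CPM in spongiotrophoblast-like nuclei of oxycodone wells and 2.90 in those of saline wells. Cubn per Afp was 0.433 (0.411 to 0.456) in yolk sac-like, 0.227 (0.188 to 0.273) in decidual stroma-like and 0.564 (0.495 to 0.642) in endothelium-like nuclei of oxycodone placenta. In both syncytiotrophoblast classes its interval covered the yolk sac value, so the ratios do not settle the question. For those 5 genes an effect of oxycodone could not be separated from uneven yolk sac tissue. By contrast, Col2a1 and Gm13727 had ratios of yolk sac-like over other nuclei of 0.231 (0.00582 to 1.30) and 0.738 (0.238 to 1.74). Of the Col2a1 UMIs, 50.7% lay in fibroblast mesenchyme-like nuclei. Gm13727 overlaps Cwc22, whose differences between wells are weighed next. Gm13727 and Cwc22 were both higher in every oxycodone than in every saline placenta well. For Gm13727 this rested on 1 UMI in oxycodone placenta 1 against 1 UMI in saline placenta 3.

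Cwc22 differed many-fold between wells of 1 group. Over 22 wells of both ages it ran from 0 to 2331 CPM in decidual stroma-like nuclei. The 0 rested on 5 nuclei of oxycodone placenta 1 at E12.5, and 2331 was in oxycodone placenta 2 at E9.5. The Cwc22 gene lies in a region whose copy number varies between mouse strains. If wells of the same order in both tissues came from 1 mouse, and gene copies differed between mice, such wells should have matched, and the permutation p of their summed difference was 0.0139 over 10 pairs. An effect of oxycodone was the biological alternative, for which no saline well should lie above the oxycodone median of its age and tissue. Of 11 saline wells 3 did, all at E12.5 and 2 of them on 9 and 5 nuclei, while at E9.5 none did. The 0.0139 does not bear on treatment, and the labels do not link wells to mice. Wells of 1 group share their treatment, so oxycodone cannot account for the spread within a group. In oxycodone decidua at E9.5, for example, Cwc22 ran from 82.3 to 1546 CPM. Whether oxycodone also raised Cwc22, and whether differences between mice gave the spread, stay open.

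Ltf was lower in all oxycodone wells at E9.5. Fewer uterine epithelial nuclei would have lowered the other epithelial markers too, and their median log2 fold was -0.082, which argues against it. In epithelial nuclei alone the ratio of Ltf CPM was 0.101 (0.0819 to 0.123), at 209 against 2074 CPM. The epithelial secretory genes C3 and Lcn2 had ratios of 0.238 and 0.171 there, and 54.2% of the oxycodone Ltf UMIs came from 1 nucleus. The ratio of 0.101 fits less Ltf per epithelial nucleus, and whether oxycodone or another difference between the mice lowered it could not be told from these wells.

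Splits of the wells that mix the groups showed how many genes other groupings give. For placenta against decidua the real split alone, 1 of 100 drawn, reached its count at each age. It gave 7822 genes against at most 2413 in another split at E9.5, and 2802 against 2007 at E12.5. At both ages that other split was the tissue split with oxycodone placenta 1 and saline decidua 3 exchanged, so its count partly reflects tissue. A random grouping was thus unlikely to give as many genes. For oxycodone there were 10 splits, too few to judge a random grouping. As many genes as in the real split came in 10 of them in E9.5 placenta (0 genes, at most 0 in another), in 10 in E9.5 decidua (0, at most 2), in 10 in decidual stroma-like nuclei of placenta (0, at most 2) and in 10 of decidua (0, at most 1). The number was 3 in endothelium-like nuclei of placenta (1, at most 4), 10 in those of decidua (0, at most 3), 2 in E12.5 placenta (7, at most 17), 10 in E12.5 decidua (0, at most 0) and 2 in P-TGC-like nuclei at E12.5 (26, at most 267). The split with 267 genes set oxycodone decidua 3, oxycodone placenta 3 and saline decidua 3 against the rest. With both decidua wells on 1 side and tissue as a covariate, it compares oxycodone placenta 3 with the other 3 placenta wells, so it shows how much 1 well can weigh in this test.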

How the results depend on the processing

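The 5000- and 200000-UMI settings, the wells under 80 nuclei, the removal of endoderm-like nuclei, the tissues taken alone, the block by well order, the per-nucleus mean for the P-TGC-like profile and the tests within classes, P-TGC-like nuclei with at least 5 per well included, were chosen after results were seen; the other tests in this part were not. Of 1796 checks of named genes in tests, 1569 kept their side of the threshold, 144 came to pass, 83 ceased to pass and 0 genes that passed reversed. Of 311 counts and shares, 105 moved, and of 1128 checks of genes by age 191 moved and 2 reversed. These tallies include the minimum of 1000 UMIs, which removed no nucleus (lowest total 2078) and so could change nothing, and clustering settings for all nuclei, which could not either. Shares of classes with oxycodone passed in no setting (0 to 0 with a well left out), but a single class could not have passed, so this says nothing about stability. Removal of the few Scrublet doublets took the genes by age from 6848 to 6846 in all nuclei and from 3434 to 3421 in decidual stroma-like nuclei. Unless named, the cause was not tested.

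At E9.5 the counts of genes in placenta were 15 in DESeq2 and 6 without the expression filter (0 to 1 with a well left out), and in decidua 19 and 12 (0 to 0). They were 20 and 126 in P-TGC-like nuclei (0 to 47), 5 and 178 in cluster 8 (0 to 0), 11 and 50 in decidual stroma-like nuclei of decidua (0 to 0), 20 and 161 in endothelium-like nuclei of placenta (0 to 4) and 5 and 114 in those of decidua (0 to 3). Without the filter decidual stroma-like nuclei of placenta gave 100 (0 to 0). Tissue at E9.5 gave 7275 to 7865 genes with a well left out, of which 7009 to 7332 were among the 7822.

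At E12.5 placenta gave 228 genes without the filter, 17 from nuclei of at least 5000 UMIs, 27 without nuclei above 200000 UMIs, 87 without wells under 80 nuclei, 0 without endoderm-like nuclei and 0 with both removals (0 to 107 with a well left out). Decidua gave 19 without the filter (0 to 0). Tissue gave 4695 in DESeq2, 4635 without the filter and 5758 without wells under 80 nuclei (1601 to 3683). P-TGC-like nuclei gave 77 in DESeq2, 348 without the filter and 3 without nuclei above 200000 UMIs (0 to 429). Without the filter the counts were 33 in chorion and labyrinth progenitor (1 to 38), 48 in decidual stroma-like nuclei (1 to 36), 345 in endothelium-like nuclei (82 to 323), 64 in glycogen trophoblast (4 to 37), 502 in parietal endoderm (194 to 384), 38 in sinusoidal giant cells (4 to 11) and 43 in spongiotrophoblast (0 to 74). DESeq2 gave 1, 116 and 4 in decidual stroma-like, endothelium-like and sinusoidal giant cell-like nuclei.

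By age, the balance of higher and lower genes turned with TMM scaling in all nuclei (4686 and 2162 to 2881 and 3296) and in decidual stroma-like nuclei (2304 and 1130 to 1206 and 1999). Decidua wells alone gave 4246 genes. Decidual stroma-like nuclei gave 6041 with a minimum of 20 UMIs, which tests more genes, and 2135 in placenta wells, where the balance also turned (991 higher and 1144 lower). Endothelium-like nuclei gave 3304 with 20 UMIs. P-TGC-like nuclei gave 3993 with 20 UMIs, 1108 without nuclei above 200000 UMIs and 335 in decidua wells, where Gad1 and Thbs2 reversed on few counts (log2 ratios 0.012 and 1.60). Their profile held 17 genes without nuclei above 200000 UMIs, of which 12 were among the 40 of the main setting. With the mean of per-nucleus CPM it held 37 genes, 23 of them among the 40.

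Clustering moved shares by age. Thinning to 1000 UMIs left 2 classes whose intervals did not overlap. Decidual stroma-like nuclei at E9.5 were 35.7% at resolution 0.5, 40.7% at 2.0 and 39.2% after thinning, and 12.4% at E12.5 at 2.0. Endothelium-like nuclei were 21.1% at E9.5 at 2.0 and after thinning alike, and at E12.5 13.3% at 0.5 and 17.4% after thinning. P-TGC-like nuclei were 5.06% at E9.5 after thinning, and at E12.5 0.855% at 0.5 and 1.77% from nuclei of at least 5000 UMIs. No cluster took this name at E9.5 at resolution 0.5 or at E12.5 after thinning, so the class depends on the clustering. Its profile and age comparison therefore have no value at 0.5.

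The metadata give wells and no replicate numbers, so a block by replicate number for oxycodone was not run. Between tissues, a block by well order, which the labels do not tie to animals, gave 8871 tissue genes at E9.5 and 2885 at E12.5. In decidua at E12.5, 5.75% of simulated 4-fold changes were found, with as few as 56899 UMIs per well and a coefficient of variation between wells of 0.452, and the parts of depth and spread were not separated.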

Other observations

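No tests were run in this part; the opioid genes were listed before the data were examined, and the clusters and the Apob, Cubn and Afp values were chosen after results were seen. Oxycodone acts on the mu opioid receptor, encoded by Oprm1, which was sparse in these nuclei. Oprm1 had 153 UMIs at E9.5, in 3.13% of nuclei, and 136 at E12.5, in 4.46%. The delta receptor gene Oprd1 had 40 and 36 UMIs, the kappa receptor gene Oprk1 6 and 5, and the nociceptin receptor gene Oprl1 7 and 6. Of the peptide genes, Penk, which encodes enkephalins, had 234 UMIs at E9.5 and 4 at E12.5, with 109 of the former in endothelium-like nuclei, at 11.3 CPM and in 6.17% of them. Pnoc, the nociceptin gene, had 7 UMIs at E9.5 and 120 at E12.5, with 35 of the latter in parietal endoderm-like nuclei, at 24 CPM. Pomc had 7 and 15 UMIs and Pdyn 1 and 0.

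Some clusters met the naming rule for no cell type. At E9.5 cluster 1 held 568 nuclei, 12.9% of all, of which 565 lay in placenta wells, and its leading genes were Gm31243, Ptprr, Pla2r1, Lifr, Il1r2 and Aldh1a3. Cluster 8 held 161 nuclei led by Sfmbt2, Pappa2, Lgr5, Slc38a4 and Peg10, genes of trophoblast. At E12.5 cluster 1 held 261 nuclei, 9.71%. Cluster 10 at E12.5 made up 69.4% of the nuclei of oxycodone placenta 1 and 73.0% of those of saline placenta 3, which both held under 80 nuclei.

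Apob per Afp was 0.306 (0.288 to 0.325) in yolk sac-like nuclei of E12.5 oxycodone placenta and 0.418 (0.326 to 0.532) in spongiotrophoblast-like, 0.344 in endothelium-like, 0.276 in decidual stroma-like and 0.2 (0.148 to 0.267) in glycogen trophoblast-like nuclei of the oxycodone wells. Cubn per Afp was 0.433 (0.411 to 0.456) in yolk sac-like nuclei, 0.530 in spongiotrophoblast-like, 0.564 (0.495 to 0.642) in endothelium-like, 0.227 (0.188 to 0.273) in decidual stroma-like and 0.270 (0.207 to 0.349) in glycogen trophoblast-like nuclei, so not every class had the ratios of yolk sac-like nuclei. Syncytiotrophoblast I- and II-like nuclei had 0.367 and 0.355 for Apob and 0.304 and 0.398 for Cubn, with intervals that covered the yolk sac values. Sinusoidal giant cell-like nuclei had 0.333 (0.225 to 0.485) for Apob and 0.254 (0.163 to 0.385) for Cubn. Afp in oxycodone wells was at 330 CPM in endothelium-like and 295 in decidual stroma-like nuclei, against 11.9 and 2.95 in saline wells.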
